A study of Homo sapiens with 12 samples.

How the data were processed

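Total RNA of 3 human breast cancer lines (MDA-MB-231, SK-BR-3 and MCF-7, per the labels), transfected by lipofectamine with a scrambled control or a miR-644 mimic, was extracted with an RNeasy Mini kit, amplified and biotin-labelled with a TargetAmp-Nano kit and hybridised to 12 one-colour bead arrays on 1 chip. Each of the 6 groups held 2 arrays. The values deposited by the authors are linear probe intensities for 47323 probes. Array medians lay between 111 and 113, maxima between 21933 and 24225 and the lowest values above 0 between 71.2 and 76.8, and 4 values (3 probes) are listed at 0. The scanner software and any background correction or scaling applied before deposition are not given in the sources used here.

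Intensities below 1 were set to 1, log2-transformed and quantile-normalised, because the upper quartiles of the arrays differed by 0.0833 log2, over the tolerance of 0.05 fixed for this step. Of the probes, 30113 carried a single gene symbol, 8 carried several and 17202 were unnamed. Entrez identifiers of 30074 probes matched the gene reference and 0 symbols were updated. Each of 20046 genes was represented by its probe with the highest mean, and 6691 genes had more than 1 probe. A model with 6 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual degrees of freedom 6, prior degrees of freedom 18.0). Tests were two-sided and moderated, with Benjamini-Hochberg adjustment over all genes within each comparison at a threshold of 0.05. The comparisons were miR-644 against control in each line, the average of the 3 lines, and the difference of the effect between lines by the moderated F test and pairwise. Genes counted as shared passed in all 3 lines with the same sign. SE values are moderated standard errors from this fit. With 2 arrays per group the permutations of a single line are too few for a test of their own.

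For gene lists, 32 lists written before the data were examined were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list, with adjustment over the 32 lists of each comparison. List members were also adjusted over the list alone. The lists cover p53 targets, G2 and M phase, DNA replication and S phase, histones, interferon, inflammation, epithelial, mesenchymal, pro- and anti-apoptotic genes, oestrogen response, the unfolded protein response, cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, proteasome, microRNA machinery, TGF-beta, Wnt, early response, CtBP partners, heat shock, autophagy, oxidative stress, antigen presentation, and HER2 amplicon, luminal, basal B and leukocyte markers.

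The genes named were chosen by a rule fixed before the data were examined. In each line and in the average they are the 10 largest rises and 10 largest falls among changed genes whose highest group mean lay above the median of all genes (log2 7.49, intensity 179), in the average with the same sign in each line. To these were added the 10 genes with the smallest F test p, a list of candidate genes, and up to 3 members of each list with the smallest p. Further list members were named after their values were seen, among them FBL, COL1A1, CCN2, KRT8, KRT18 and MCM7, as were the line markers GRB7, PGAP3, STARD3, TFF1 and CAV1.

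The pipeline was tested on simulated data with 200 changed genes of 20046. At a change of 0.5 log2 it recovered 95%, 94%, 88% and 100% of them in the 3 lines and the average, and at 1 log2 it recovered 100% in each, with 5.31%, 5.34%, 4.08% and 3.60% false calls. A proteasome list shifted by 0.2 log2 was called, and 0 other lists were. The simulated noise was independent between genes and few genes changed. The simulation therefore could not show false list calls that come from correlated members. Alternatives planned beforehand were another scaling to equal medians, a filter on genes below the median level, every probe by itself, an intensity trend in eBayes, array weights, the replicate number as a block, leaving out each array, a 1.5-fold minimum, fits on the 4 arrays of a line, camera with an estimated correlation, fry, and other CTBP1 probes. Added after seeing the data were log2 values without quantile normalization, a normexp background, zeros as missing and fits without the arrays labelled MCF-7. A planned analysis of genes with miR-644 seed sites in their 3 prime UTR was not analysed here, since no transcript sequences were at hand. Chip position was not modelled, because it coincides with treatment.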

Results

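Gene expression was measured on 12 one-colour arrays of biotin-labelled total RNA from 3 breast cancer cell lines. MDA-MB-231 is a mesenchymal, oestrogen receptor-negative line, SK-BR-3 carries an amplified HER2 (ERBB2) gene, and MCF-7 is known as an oestrogen receptor-positive line without that amplification. Cells of each line were transfected with a mimic of the microRNA miR-644 or with a scrambled control mimic, and 2 replicate arrays were deposited for each of the 6 groups. The design asks what miR-644 changes within each line. Each array gave 47323 probe intensities, with array medians between 111 and 113 and a signal floor near 75, so the intensities of genes near the floor carry background. Replicates correlated at r = 0.996 to 0.997 across probes, and the precision is limited by the number of arrays. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. All 12 arrays lay on 1 chip with the miR-644 arrays at one end and the controls at the other, so that chip position and treatment cannot be told apart.

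The control arrays were first compared between lines, because the array names of the line labelled MCF-7 carry another letter code (BT) than that label. On the control arrays labelled MCF-7, ERBB2 reached a mean intensity of 18180, against 19010 in SK-BR-3 and 823 in MDA-MB-231. Its fitted difference from MDA-MB-231 was 4.49 log2 (adjusted p = 6.97e-23), and is compressed to an unknown extent because the probe lies near the array maxima of 21933 to 24225. Its level cannot be compared closely with SK-BR-3 for the same reason, and neighbouring genes under that ceiling differed, with PGAP3 1.33 and PSMD3 1.01 log2 higher and CDK12 lower (-1.89). Of the 10 measured genes around ERBB2 on 17q12 that are co-amplified in HER2-positive tumours, 9 were over 1 log2 higher on the arrays labelled MCF-7 than in MDA-MB-231, among them GRB7 at 5731 against 125, PGAP3 at 8094 against 286 and STARD3 at 3056 against 390. The same arrays carried oestrogen receptor-positive markers. ESR1, the oestrogen receptor, stood at 620 against 103 in MDA-MB-231 and 107 in SK-BR-3, the progesterone receptor gene PGR at 546 against 96.2 and 99.9, and the oestrogen-induced TFF1 at 14760 against 105 and 132. Of 14 luminal markers, 13 were over 1 log2 higher than in MDA-MB-231. MDA-MB-231 carried the basal B mesenchymal genes, with VIM at 19470, PLAU at 15330 and CAV1 at 9339, and 14 of 16 such markers were over 1 log2 lower on the arrays labelled MCF-7. The 14 leukocyte markers had a median intensity of 111 over all 12 arrays against 136 for all genes. On the control arrays CSF1R reached 373 in SK-BR-3 and 186 in MDA-MB-231, and CD14 reached 203 in MDA-MB-231. Every statement on that line therefore refers to the arrays labelled MCF-7, and a direction given for them is that of the RNA on these arrays.

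**Figure D1:**
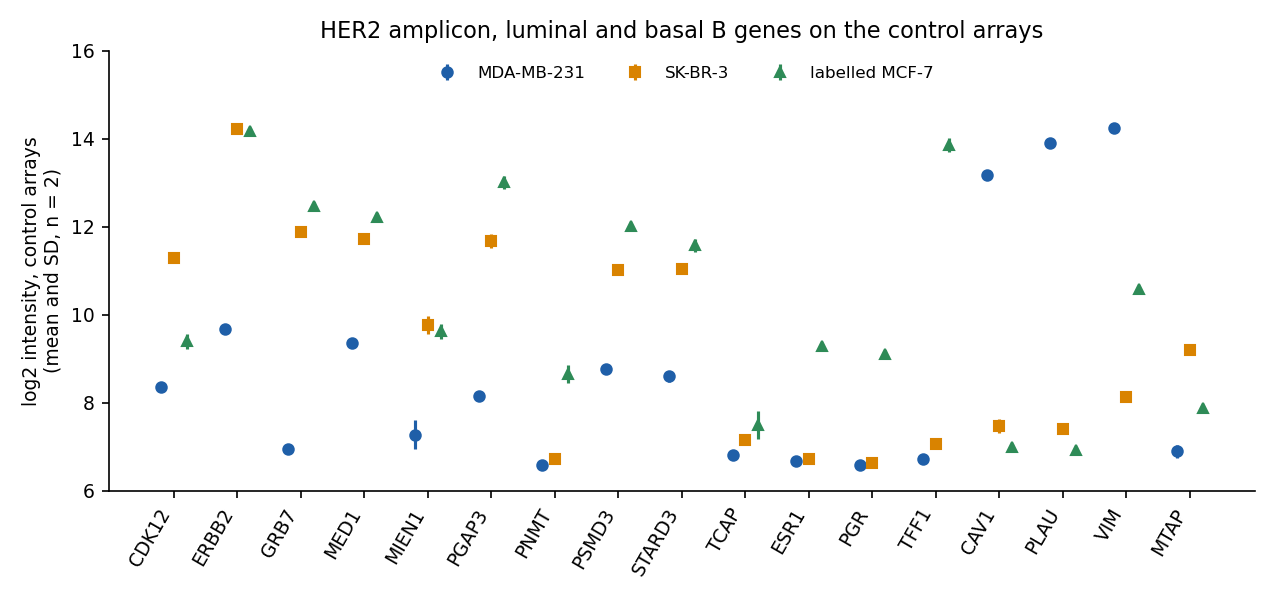
Log2 intensity (y axis) of the 10 HER2 amplicon genes, 3 oestrogen receptor-positive markers, 3 basal B markers and MTAP (x axis) on the control arrays of each line, as the mean and SD of 2 arrays. ERBB2 lies at 14.18 on the arrays labelled MCF-7 and 14.22 in SK-BR-3, against 9.69 in MDA-MB-231, while ESR1, PGR and TFF1 are high on the arrays labelled MCF-7.

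CTBP1, the transcriptional corepressor for which miR-644 has been studied, was lower after miR-644 in every line. Its intensity dropped from 1908 and 2076 on the control arrays to 597 and 630 in MDA-MB-231, from 907 and 952 to 472 and 435 in SK-BR-3, and from 1657 and 1777 to 963 and 962 on the arrays labelled MCF-7. The log2 fold changes were -1.73 ± 0.09 (SE, n = 2 arrays per group; limma, adjusted p = 3.41e-13), -1.06 ± 0.09 (adjusted p = 6.00e-09) and -0.86 ± 0.09 (adjusted p = 1.39e-07). The change differed between lines (moderated F test, adjusted p = 4.05e-05). A second, dimmer CTBP1 probe (115 to 339 over the arrays) fell by 0.58, 0.69 and 0.76 log2. Another dim probe (111 to 261) fell by 0.40 in MDA-MB-231 and 0.45 in SK-BR-3. Its change of -0.28 on the arrays labelled MCF-7 did not pass (adjusted p = 0.0678). Background can compress the changes of both dim probes. The paralogue CTBP2 did not pass in any line, with log2 fold changes of -0.14, 0.17 and -0.05. Its main probe was dim (182 to 359 over the arrays) and its other probes lay near background (105 to 161). A fall of CTBP2 could therefore be compressed or hidden. Among 17 measured genes of CtBP complexes, CTBP1 included, the histone demethylase gene KDM1A fell by 0.71 log2 and the deacetylase gene HDAC1 by 0.55 in MDA-MB-231, while ZNF217 rose by 0.61. As a list these genes did not move more than other genes (mean log2 fold change -0.10 in the average of the lines, camera adjusted p = 0.222). By fry, which tests them against no change, the list was called lower (adjusted p = 2.17e-05). In the average 4 were lower and 1 higher by either adjustment, over all genes or adjusted over the list alone. CTBP1 is among the falls, and the median of the list was -0.01. Fry was not run without CTBP1, so its call says little about the partners.

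**Figure D2:**
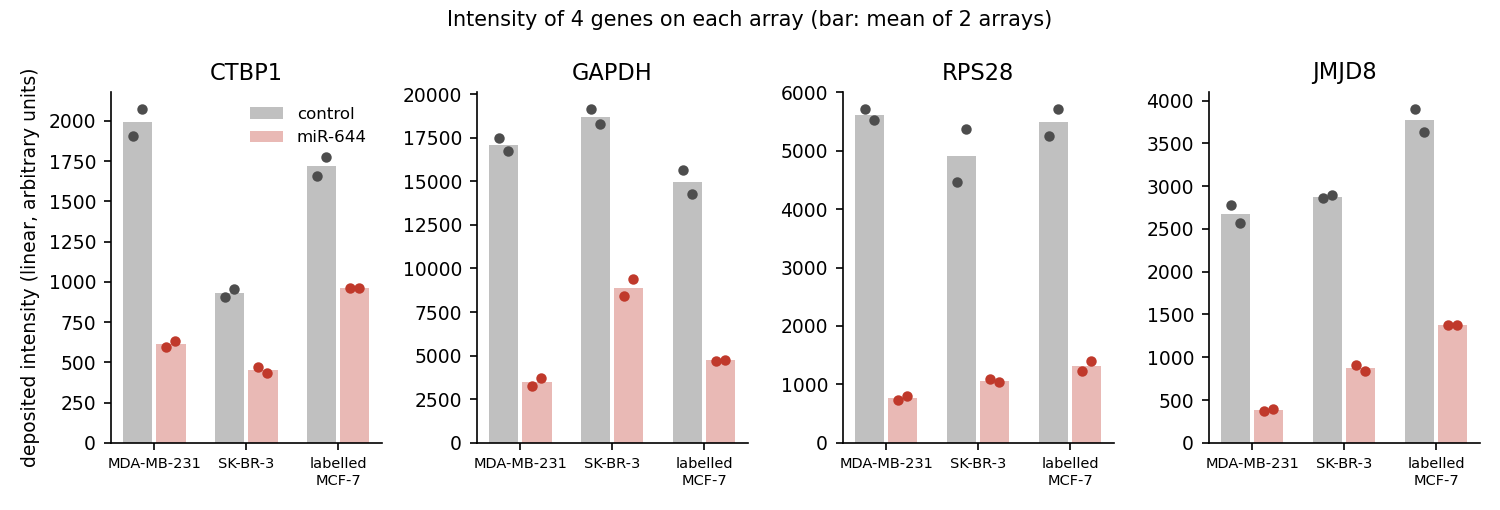
Deposited linear intensity (y axis, from 0) of CTBP1, GAPDH, RPS28 and JMJD8 by line (x axis), with a point per array and a bar for the mean of 2 arrays, in grey for control and red for miR-644. In each line both miR-644 arrays lie below both control arrays, for example at 726 and 803 against 5721 and 5519 for RPS28 in MDA-MB-231.

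MDA-MB-231 responded with 5021 changed genes of 20046 tested, 2582 higher and 2439 lower. By the main probe of each gene, RPS28, which encodes a protein of the small ribosomal subunit, fell most (7.60-fold lower, log2 fold change -2.93 ± 0.10). JMJD8, a jumonji-domain protein gene (-2.83 ± 0.09), and the collagen-modifying enzyme gene PLOD1 (-2.62 ± 0.10) followed. GAPDH, a glycolytic enzyme often used as a reference gene, fell by 2.31 log2. That probe is near the ceiling on control arrays, and a GAPDH probe further below it fell by 2.98 in MDA-MB-231, 1.88 in SK-BR-3 and 2.08 on the arrays labelled MCF-7, so that the rank of GAPDH depends on the probe. The actin-bundling protein gene TRIOBP, TM9SF4, CCDC92, BCKDK, which encodes the kinase of branched-chain amino acid breakdown, and the metalloprotease gene ADAM19 fell by 2.25 to 2.40 log2. The largest rises were DAAM1, a formin of planar cell polarity (3.83-fold higher, 1.94 ± 0.11), and IFIH1, the cytosolic sensor of double-stranded RNA also called MDA5 (1.82 ± 0.10). They were followed by ENC1 (1.73), SCOC (1.66), the glucosylceramide synthase gene UGCG (1.65), TUFT1 (1.61), the complex I subunit gene NDUFB5 (1.61), PGM2 (1.61), UHMK1 (1.60) and PLAC8 (1.57). The adjusted p-values of these 20 genes lay at or below 4.97e-11.

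Genes of the unfolded protein and integrated stress responses fell together in MDA-MB-231. Of 29 measured, 22 fell and 1 rose, or 22 and 2 adjusted over the list alone (mean log2 fold change -0.51, camera adjusted p = 9.71e-11, and adjusted p = 0.0135 with an estimated correlation). They included the stress-induced pseudokinase gene TRIB3 (-1.47 ± 0.09), the transcription factor gene DDIT3 (-1.45 ± 0.10) and EDEM1 of protein quality control in the endoplasmic reticulum (-1.23 ± 0.09). Interferon-response genes rose, with 18 of 34 higher and 1 lower by either adjustment, over all genes or adjusted over the list alone (mean 0.41, adjusted p = 4.17e-07, and 0.0135 as the adjusted p with an estimated correlation). IFIH1 led them, with IFIT1 (1.44 ± 0.10) and OASL (1.19 ± 0.11) next. Of 20 genes of cholesterol synthesis, 12 rose and 0 fell, and 15 rose adjusted over the list alone (mean 0.37, adjusted p = 9.41e-06, and adjusted p = 0.0184 with an estimated correlation). IDI1 (1.04 ± 0.11), the squalene epoxidase gene SQLE (0.72 ± 0.09) and ACAT2 (0.65 ± 0.09) had the smallest p. These lists were the ones whose call was kept with an estimated correlation.

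Other lists passed the test in MDA-MB-231 with the preset correlation alone. Ribosome biogenesis rose, with 17 of 28 genes higher and 2 lower (18 and 2 adjusted over the list alone). WDR12 (1.10) and RRP12 (0.91) were among them, while the fibrillarin gene FBL fell by 0.79 (camera adjusted p = 6.58e-05, adjusted p = 0.0882 with an estimated correlation). Among 32 p53 targets 11 rose and 2 fell by either adjustment, led by TP53I3 (1.07), GDF15 (1.00) and TP53INP1 (0.91), with a camera adjusted p = 0.00616 and an adjusted p = 0.0837 with an estimated correlation. Of 29 respiratory chain genes 8 rose and 2 fell (10 and 2 adjusted over the list alone), with NDUFB5, SDHD (0.92) and ATP5F1C (0.63) in front (camera adjusted p = 0.00616, adjusted p = 0.140 with an estimated correlation). The oxidative stress list, in which 9 of 22 rose and 1 fell (9 and 2 adjusted over the list alone), held the metallothionein gene MT1F (1.18) and the cystine transporter gene SLC7A11 (0.67), with a camera adjusted p = 0.0122 and an adjusted p = 0.168 with an estimated correlation. Of 17 antigen presentation genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), such as CD74 (0.78) and TAP1 (0.57), with a camera adjusted p = 0.0265 and an adjusted p = 0.160 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.120) and without miR-644 replicate 2 (adjusted p = 0.0541). With dim genes left out, the respiratory chain (adjusted p = 0.0647), oxidative stress (0.163) and antigen presentation (0.109) calls were lost. Glycolysis and hypoxia genes fell, with 10 of 27 lower and 2 higher by either adjustment, with a camera adjusted p = 0.00583 and an adjusted p = 0.160 with an estimated correlation. Besides GAPDH these were led by the regulator gene PFKFB3 (-1.35) and the glucose transporter gene SLC2A1 (-1.20).

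SK-BR-3 had 2825 changed genes, 1404 higher and 1421 lower. By the main probes RPS28 fell most (4.70-fold lower, log2 fold change -2.23 ± 0.10), followed by PCP4, a regulator of calmodulin (-2.03 ± 0.10), and the growth factor gene TGFB3 (-1.89 ± 0.09). JMJD8 (-1.74), the purine salvage enzyme gene APRT (-1.73), RPL23A of the large ribosomal subunit (-1.66), SSR1 of the translocon at the endoplasmic reticulum (-1.65), ERGIC1 (-1.65), the reticulon gene RTN3 (-1.59) and CTDSPL (-1.50) completed the 10 largest falls. GAPDH is not among them by its main probe (-1.10), but by its other probes (-1.88 and -1.62) it would be. The largest rises were the metallothionein gene MT1G (3.09-fold higher, 1.63 ± 0.10), the keratin gene KRT15 (1.62 ± 0.10), NTN4 (1.54 ± 0.10) and the retinaldehyde dehydrogenase gene ALDH1A3 (1.54 ± 0.09). The prostaglandin E synthase gene PTGES (1.43), S100A3 (1.41), the chemokine gene CCL2 (1.36), DHRS3 (1.33), the ubiquitin ligase gene FBXO32 (1.30) and SPATS2L (1.23) also rose. These 20 genes had adjusted p-values at or below 5.91e-10. Without miR-644 replicate 1 the number of changed genes in SK-BR-3 dropped to 1842.

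Cell cycle genes of the G2 and M phases fell in SK-BR-3. Of 30 measured, 18 fell and 0 rose, and 23 fell adjusted over the list alone (mean log2 fold change -0.38, camera adjusted p = 4.51e-14, but adjusted p = 0.0559 with an estimated correlation). The mitotic kinesin genes KIF20A (-0.91 ± 0.09) and CENPE (-0.68 ± 0.09) and the spindle gene DLGAP5 (-0.78 ± 0.10) had the smallest p. In contrast, 9 of 34 DNA replication and S phase genes rose and 2 fell by either adjustment, with POLA1 (0.58) and MCM7 (0.44) higher and RRM2 (-0.55) lower. That list (camera adjusted p = 0.00481) lost its call without control replicate 2 (adjusted p = 0.0690) and had an adjusted p = 0.138 with an estimated correlation. Histone genes were lower as a list of 15 (mean -0.21, adjusted p = 0.00199, and adjusted p = 0.0559 with an estimated correlation), although 2 fell by themselves, H2BC11 (-0.90) and H2AC11 (-0.30), and 4 fell adjusted over the list alone. H2AC11 did not pass without control replicate 1 (adjusted p = 0.337), without miR-644 replicate 1 (0.265) or without miR-644 replicate 2 (0.0655). The limma call of H2AC11 was also lost with equal medians (adjusted p = 0.0739) and with every probe by itself (0.0531). The same held with an intensity trend (0.0564) and in the fit on the 4 arrays of the line (0.0594). No list in SK-BR-3 kept its call with an estimated correlation.

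Immune and early response genes were higher in SK-BR-3. Of 17 antigen presentation genes 7 rose and 0 fell (8 and 1 adjusted over the list alone), with the peptide transporter gene TAP1 (1.21 ± 0.09) and the immunoproteasome genes PSMB8 (1.08 ± 0.09) and PSMB10 (1.09 ± 0.09) in front (camera adjusted p = 0.000381, adjusted p = 0.0559 with an estimated correlation). Among 34 interferon-response genes 7 rose and 2 fell (12 and 2 adjusted over the list alone), including IFIH1 and ISG15 (1.01), with a camera adjusted p = 0.00325 and an adjusted p = 0.0559 with an estimated correlation. The inflammatory genes CCL2, TNF (0.94) and SOD2 (0.40) stood among 7 of 23 that rose by either adjustment (camera adjusted p = 0.00302, adjusted p = 0.0710 with an estimated correlation). Of 25 early response and MAPK genes 10 rose and 3 fell (13 and 3 adjusted over the list alone), with JUN (0.93) and DUSP5 (0.92) higher and the feedback regulator gene SPRED2 lower (-1.04), a camera adjusted p = 0.000202 and an adjusted p = 0.0559 with an estimated correlation. Of 22 oxidative stress genes 6 rose and 1 fell (9 and 1 adjusted over the list alone), with MT1G and the ferritin gene FTL (0.85) in front (camera adjusted p = 0.000381, adjusted p = 0.0571 with an estimated correlation). Ribosome biogenesis rose too, with 10 of 28 higher and 1 lower (14 and 1 adjusted over the list alone), such as MYC (0.72) and WDR12 (0.65), against ODC1 (-0.62), with a camera adjusted p = 0.000130 and an adjusted p = 0.0571 with an estimated correlation.

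Line identity genes moved in SK-BR-3 as well. Of 16 basal B markers 5 rose and 0 fell (7 and 0 adjusted over the list alone), such as PLAU (0.99 ± 0.09), CD44 (0.95 ± 0.10) and ANXA1 (0.68 ± 0.09), with a camera adjusted p = 0.000381 and an adjusted p = 0.0559 with an estimated correlation. Among 14 luminal markers 5 fell and 2 rose (6 and 2 adjusted over the list alone). AGR2 (-1.08 ± 0.10), SPDEF (-0.86 ± 0.09) and the pioneer factor gene FOXA1 (-0.72 ± 0.09) fell, while the keratin genes KRT8 (0.57) and KRT18 (0.42) rose (camera adjusted p = 0.00481, adjusted p = 0.0571 with an estimated correlation). Of 25 epithelial junction genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), led by ELF3 (1.21) and CLDN3 (0.60), with a camera adjusted p = 0.00893 and an adjusted p = 0.0710 with an estimated correlation. The TGF-beta list rose with 4 of 23 higher and 0 lower (5 and 0 adjusted over the list alone), among them ID3 (0.88) and BAMBI (0.62), with a camera adjusted p = 0.00481. Its call was lost without control replicate 2 (adjusted p = 0.0510), and it had an adjusted p = 0.127 with an estimated correlation. Lists with mean changes within 0.15 log2 passed as well. Respiratory chain genes (2 of 29 higher, 0 lower, by either adjustment) and autophagy genes (7 of 25 higher and 0 lower, 9 and 1 adjusted over the list alone) passed as higher at camera adjusted p = 0.0293 and 0.0430. Fatty acid synthesis (1 of 15 higher and 3 lower, 1 and 5 adjusted over the list alone), unfolded protein response (5 of 29 and 11, 6 and 12 adjusted over the list alone) and heat shock genes (2 of 17 and 4, by either adjustment) passed as lower at 0.0296, 0.0402 and 0.0453. In the same order their adjusted p with an estimated correlation was 0.127, 0.109, 0.105, 0.138 and 0.121, and all of these calls were lost without control replicate 2 and without miR-644 replicate 1. The autophagy and heat shock calls were also lost without control replicate 1 (adjusted p = 0.0704 and 0.0939), and the heat shock call without either miR-644 replicate of MDA-MB-231 (0.0510). With dim genes left out all of them were lost, with adjusted p from 0.102 to 0.158, and with equal medians the unfolded protein response (0.0571) and heat shock (0.0732) calls. The number of lists past the test dropped from 18 to 11 without control replicate 2.

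On the arrays labelled MCF-7, 3231 genes changed, 1688 higher and 1543 lower. By the main probes RPS28 again fell most (4.20-fold lower, log2 fold change -2.07 ± 0.10), followed by APRT (-1.82 ± 0.11), RPL23A (-1.77 ± 0.10), GAPDH (-1.66 ± 0.09) and SSR1 (-1.55 ± 0.11), while the dimmer GAPDH probe fell about as much as RPS28. The carnitine acetyltransferase gene CRAT (-1.54), SRARP (-1.53), the cell adhesion gene CEACAM6 (-1.53), the cytokinesis gene CEP55 (-1.48) and COLGALT1 (-1.47) also fell. The largest rises were HERC5, an interferon-induced ISG15 ligase (3.50-fold higher, 1.81 ± 0.10), the transcription factor gene TWIST1 (1.74 ± 0.09), VIM, which encodes vimentin (1.54 ± 0.09), the Wnt inhibitor gene DKK1 (1.46 ± 0.10) and FOS (1.46 ± 0.13). CITED4 (1.45), FBXO32 (1.41), ID3 (1.39) and SRPK2 (1.36) followed. TELO2 was listed among them at 1.68 ± 0.49 (adjusted p = 0.0184), but one control array is listed at 0 for it, and with that value left out its change was 0.05 (adjusted p = 0.926). It did not pass either without miR-644 replicate 1 (adjusted p = 0.101) or replicate 2 (0.0816). Leaving TELO2 aside, these genes had adjusted p-values at or below 1.76e-08.

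Cell cycle genes fell broadly on the arrays labelled MCF-7. Of 34 genes of DNA replication and the S phase, 25 fell and 0 rose, and 26 fell adjusted over the list alone (mean log2 fold change -0.51, camera adjusted p = 2.13e-21, and adjusted p = 0.0180 with an estimated correlation). GINS2 of the replicative helicase (-1.42 ± 0.09), the ribonucleotide reductase gene RRM2 (-1.39 ± 0.10) and the thymidine kinase gene TK1 (-1.32 ± 0.09) led. Of 30 G2 and M phase genes 26 fell and 0 rose, and 29 fell adjusted over the list alone (mean -0.44, adjusted p = 2.10e-19, but adjusted p = 0.0781 with an estimated correlation), among them the kinesin gene KIF11 (-0.81 ± 0.10), the survivin gene BIRC5 (-0.74 ± 0.09) and NUSAP1 (-0.60 ± 0.09). Histone genes went the other way, with 7 of 15 higher and 1 lower (7 and 2 adjusted over the list alone), led by H2BC5 (1.16), H2AC6 (1.30) and H4C8 (0.77), with a camera adjusted p = 0.00374 and an adjusted p = 0.0781 with an estimated correlation. Among 32 p53 targets 10 rose and 2 fell (11 and 2 adjusted over the list alone), with GADD45A (1.05), TP53INP1 (0.88) and XPC (0.64) in front and CDKN1A, which encodes the cell cycle inhibitor p21, at 0.73 ± 0.11 (adjusted p = 4.05e-05). That list had a camera adjusted p = 0.00679 and an adjusted p = 0.0781 with an estimated correlation.

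Mesenchymal genes rose as a list of 29 on these arrays, with 6 higher and 1 lower (7 and 1 adjusted over the list alone), a camera adjusted p = 0.0206 and an adjusted p = 0.172 with an estimated correlation. Besides TWIST1 and VIM these were CCN1 (1.09), COL1A1 (0.84), the N-cadherin gene CDH2 (0.69) and CCN2 (0.53). The TGF-beta list rose with 7 of 23 higher and 1 lower (7 and 2 adjusted over the list alone), such as JUNB (1.06) and ID1 (1.02), with a camera adjusted p = 0.0183. Its call was lost without control replicate 1 (adjusted p = 0.0748), and it had an adjusted p = 0.242 with an estimated correlation. Of 14 luminal markers 6 fell and 3 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.0232), and the call was lost without control replicate 2 (adjusted p = 0.0631). MYB (-0.82) and ESR1 (-0.75) fell, whereas PGR rose by 0.68. The luminal list had an adjusted p = 0.126 by camera with an estimated correlation. Autophagy and lysosome genes rose, with 9 of 25 higher and 0 lower (9 and 2 adjusted over the list alone), such as GABARAPL1 (0.62) and NPC1 (0.52), with a camera adjusted p = 0.0133 and an adjusted p = 0.0895 with an estimated correlation. Fatty acid synthesis genes fell, with 6 of 15 lower and 1 higher (7 and 1 adjusted over the list alone), such as ELOVL6 (-0.84) and ACLY (-0.80), with a camera adjusted p = 0.0134 and an adjusted p = 0.0958 with an estimated correlation. Pro-apoptotic genes passed as a higher list with 5 of 25 higher and 2 lower (7 and 2 adjusted over the list alone), led by BMF (0.91) and the death receptor gene TNFRSF10B (0.58), at a camera adjusted p = 0.0409. That call was lost without control replicate 2 (adjusted p = 0.0845) and without miR-644 replicate 2 (0.147), and had an adjusted p = 0.129 with an estimated correlation. When genes below the median level were left out, 4 lists passed instead of 10. The histone (adjusted p = 0.0565), fatty acid (0.0565), autophagy (0.0675), TGF-beta (0.0937), luminal (0.113) and pro-apoptotic (0.347) calls were lost.

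**Figure D3:**
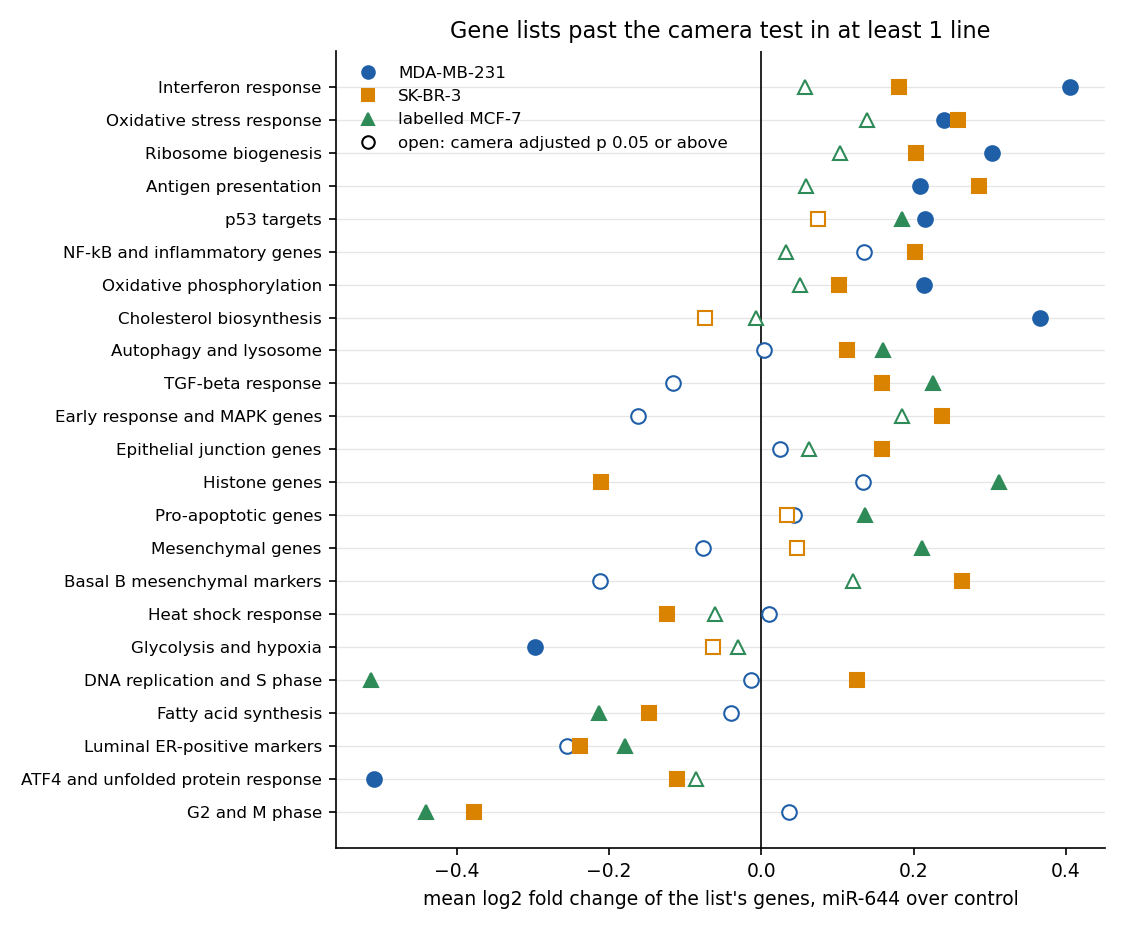
Mean log2 fold change, miR-644 over control (x axis), of the gene lists past the camera test in at least 1 line (y axis), with circles for MDA-MB-231, squares for SK-BR-3 and triangles for the arrays labelled MCF-7. Filled symbols passed with the preset correlation, and open ones did not. The S phase list lies at -0.51 on the arrays labelled MCF-7 and at 0.13 in SK-BR-3, and the unfolded protein response list at -0.51 in MDA-MB-231.

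Averaged over the 3 lines, miR-644 changed 5602 genes, 3033 higher and 2569 lower. By main probes, the largest falls with one direction in each line were RPS28 (5.31-fold lower, log2 fold change -2.41 ± 0.06), JMJD8 (-2.01 ± 0.05), RPL23A (-1.81 ± 0.06), SSR1 (-1.75 ± 0.06) and GAPDH (-1.69 ± 0.05), followed by TRIOBP (-1.67), COLGALT1 (-1.66), PLOD1 (-1.61), TM9SF4 (-1.59) and the nucleolar gene RRP36 (-1.56). By either of its other probes GAPDH fell by at least 2.05 in the average and would rank above JMJD8. The largest rises were the splicing regulator gene PTBP2 (2.26-fold higher, 1.18 ± 0.05), UHMK1 (1.11 ± 0.06), FBXO32 (1.09 ± 0.05), CCN1, a matrix-associated signalling protein gene (1.08 ± 0.06), and PDLIM7 (1.07 ± 0.05). IFIH1 (1.06), ENC1 (1.06), UGCG (1.05), ALDH1A3 (1.05) and EXOSC5 of the RNA exosome (1.00) followed, and the adjusted p-values of these 20 genes lay at or below 5.82e-13. Of the changes of at least 1.5-fold, 400 were falls and 159 were rises. Past the test with the same sign in all 3 lines were 322 rises and 521 falls, where independent lists of the same sizes would share 15.2 and 13.3. With the arrays labelled MCF-7 left out, an alternative chosen after seeing the data, 1526 genes changed the same way in MDA-MB-231 and SK-BR-3. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.48 between MDA-MB-231 and SK-BR-3, 0.37 between MDA-MB-231 and the arrays labelled MCF-7, and 0.49 between SK-BR-3 and the arrays labelled MCF-7.

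In the average of the lines, G2 and M phase genes were lower, with 17 of 30 lower and 1 higher (18 and 1 adjusted over the list alone), a camera adjusted p = 5.18e-09 and an adjusted p = 0.0977 with an estimated correlation. In MDA-MB-231 9 rose and 4 fell (10 and 5 adjusted over the list alone, mean 0.04, camera adjusted p = 0.644). The difference of the list from MDA-MB-231 passed by camera for both other lines (adjusted p = 2.45e-10 for SK-BR-3 and 3.66e-11 for the arrays labelled MCF-7), but not with an estimated correlation (adjusted p = 0.0914 and 0.0878). In the average BIRC5 (-0.71 ± 0.05), which fell in MDA-MB-231 too, KIF20A (-0.71 ± 0.05) and the proliferation marker gene MKI67 (-0.54 ± 0.06) had the smallest p. Unfolded protein response genes were lower, with 19 of 29 lower and 4 higher by either adjustment, such as TRIB3 and DDIT3 (-0.88), with a camera adjusted p = 7.43e-06 and an adjusted p = 0.0652 with an estimated correlation. Ribosome biogenesis was higher, with 16 of 28 higher and 1 lower by either adjustment (camera adjusted p = 3.46e-05, adjusted p = 0.0780 with an estimated correlation), as were interferon-response genes, with 17 of 34 higher and 2 lower by either adjustment (camera adjusted p = 6.23e-05, adjusted p = 0.0652 with an estimated correlation). Among 32 p53 targets 15 rose and 2 fell (17 and 3 adjusted over the list alone), such as TP53I3 (0.65) and GADD45A (0.69), with a camera adjusted p = 0.00161 and an adjusted p = 0.0652 with an estimated correlation. The oxidative stress list (12 of 22 higher and 2 lower), the antigen presentation list (8 of 17 and 1) and, with counts of 13 and 2 and of 11 and 1 adjusted over the list alone, the respiratory chain list (10 of 29 and 2) and the inflammatory list (10 of 23 and 1) were also higher. The counts of the first pair were the same adjusted over the list alone. Their camera adjusted p-values were 0.000870, 0.00262, 0.00491 and 0.0122, with adjusted p = 0.0846, 0.0811, 0.0977 and 0.133 with an estimated correlation. With dim genes left out the respiratory chain (0.0545) and inflammatory (0.0800) calls were lost. Luminal markers were lower (8 of 14 lower and 3 higher, 10 and 3 adjusted over the list alone, camera adjusted p = 0.00345), led by AGR2 (-0.97) and SPDEF (-0.78), with an adjusted p = 0.0780 with an estimated correlation. HER2 amplicon genes were lower too (5 of 10 lower and 0 higher, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0429, and adjusted p = 0.133 with an estimated correlation). That call was lost without MDA-MB-231 control replicate 2 (adjusted p = 0.0588) or miR-644 replicate 2 (0.0619), without SK-BR-3 miR-644 replicate 2 (0.0666), without MCF-7-labelled control replicate 1 (0.0722) and without all arrays labelled MCF-7 (0.0561). It was also lost with equal medians (0.0543) and with dim genes left out (0.157). S phase genes were lower in the average (mean -0.13, 11 of 34 lower and 2 higher by either adjustment, camera adjusted p = 0.00433, adjusted p = 0.154 with an estimated correlation), but the mean was 0.06 with the arrays labelled MCF-7 left out (camera adjusted p = 0.295). Lists that did not pass by camera in any line or in the average were the ribosomal proteins, the proteasome, oestrogen-induced genes, Wnt targets, anti-apoptotic genes, CtBP partners, the microRNA machinery and leukocyte markers, with camera adjusted p between 0.0832 and 0.990.

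Effects differed between lines for 4109 genes (moderated F test of equal changes, adjusted p under 0.05). With the arrays labelled MCF-7 left out, MDA-MB-231 and SK-BR-3 differed for 2675 genes. The genes with the smallest p included several that moved in opposite directions. The urokinase gene PLAU fell in MDA-MB-231 (-1.47 ± 0.09) and rose in SK-BR-3 (0.99 ± 0.09). DKK1 fell in SK-BR-3 (-0.99 ± 0.10) and rose in MDA-MB-231 (0.93 ± 0.10) and on the arrays labelled MCF-7 (1.46 ± 0.10). ID3, an inhibitor of DNA binding, fell in MDA-MB-231 (-1.14 ± 0.11) and rose in the other lines (0.88 ± 0.11 and 1.39 ± 0.11). GPER1, a membrane receptor gene linked to oestrogen, fell in MDA-MB-231 (-1.46) and rose on the arrays labelled MCF-7 (0.79). ADAM19, BCKDK and FLRT2 had their larger falls in MDA-MB-231 (-2.25, -2.25 and -1.76), PCP4 in SK-BR-3 (-2.03), and TGFB3 fell in SK-BR-3 and on the arrays labelled MCF-7 (-1.89 and -1.38), while TWIST1 rose on the arrays labelled MCF-7 (1.74). The F test gave an adjusted p at or below 1.47e-09 for all of these. A gene near background cannot fall visibly, and in some lines no array reached the median level of all genes (136). This held for FLRT2 outside MDA-MB-231, for PCP4 in MDA-MB-231, and for ADAM19 and PLAU on the arrays labelled MCF-7. TGFB3 in MDA-MB-231 lay little above that level (141 to 153), so that a fall could hardly be seen there. TWIST1 lay below that level in MDA-MB-231 and SK-BR-3, where background could also hide a rise. The differences of FLRT2 and PCP4 therefore say little about miR-644, as PCP4 was also dim on the arrays labelled MCF-7, while those of ADAM19 and PLAU hold between MDA-MB-231 and SK-BR-3. Calls in opposite directions were found for 469 genes. Pairwise, 2681 genes differed between SK-BR-3 and MDA-MB-231, 3479 between the arrays labelled MCF-7 and MDA-MB-231, and 1117 between the arrays labelled MCF-7 and SK-BR-3.

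**Figure D4:**
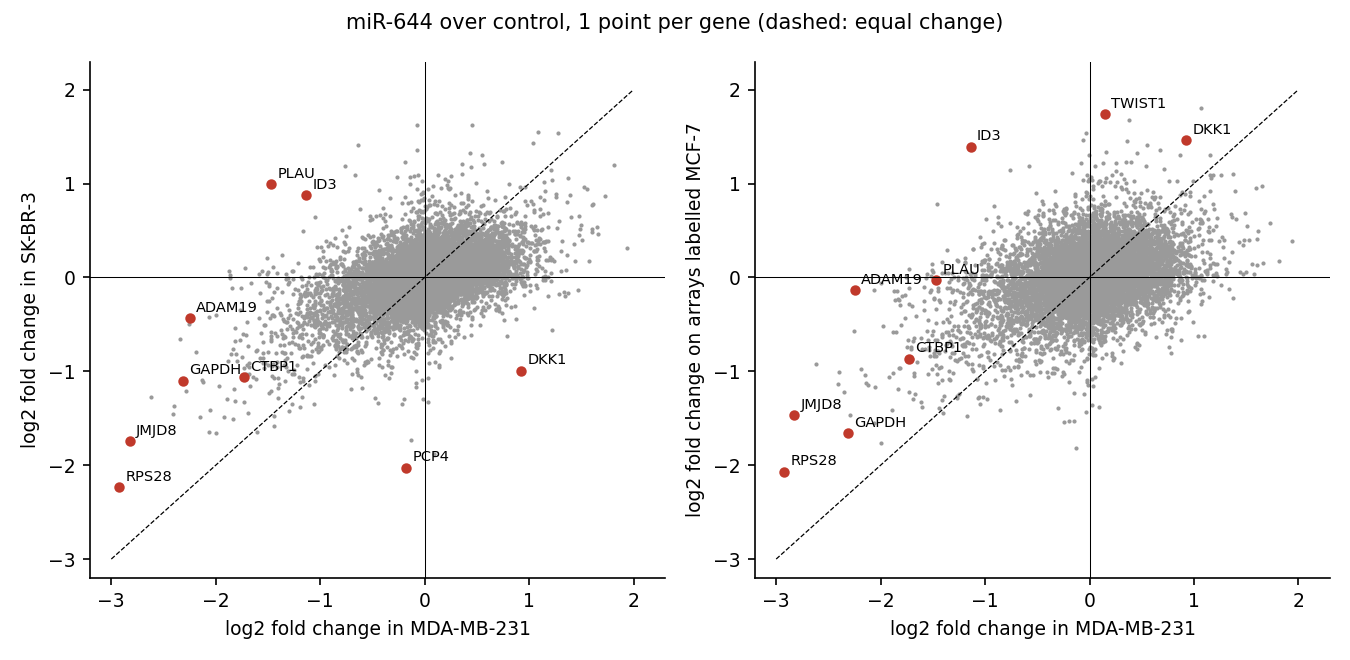
Log2 fold change, miR-644 over control, in MDA-MB-231 (x axis) against SK-BR-3 (left panel, y axis) and against the arrays labelled MCF-7 (right panel, y axis), with a point per gene and a dashed line of equal change. RPS28, JMJD8 and GAPDH lie low in every line, whereas PLAU and ID3 lie at -1.47 and -1.14 in MDA-MB-231 and at 0.99 and 0.88 in SK-BR-3.

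The remaining genes fixed in advance concern apoptosis, epithelial-to-mesenchymal transition and reference levels. BIRC5, which encodes survivin, fell in each line by 0.84, 0.56 and 0.74 log2 (SE 0.09 each), and the changes did not differ past the threshold (F test adjusted p = 0.256). A dimmer BIRC5 probe had -0.15, -0.27 and -0.34 and passed on the arrays labelled MCF-7 alone (adjusted p = 0.0177), and this difference between lines was not tested for it. The main probes of the p53 targets PMAIP1, BBC3 and MDM2 did not pass in any line, with log2 fold changes between -0.11 and 0.23. MDM2 lay near background in every line (120 to 141), as did PMAIP1 in SK-BR-3 (99.9 to 108). A change of these transcripts could be hidden there. Another PMAIP1 probe rose in MDA-MB-231 (0.37, adjusted p = 0.00410). CDKN1A rose on the arrays labelled MCF-7, and its changes of 0.12 in MDA-MB-231 and 0.25 in SK-BR-3 did not pass (F test adjusted p = 0.0146). By its main probe MCL1 rose in MDA-MB-231 (0.43, adjusted p = 0.00302), and another MCL1 probe rose in all 3 lines (0.55, 0.67 and 0.50, adjusted p = 9.22e-05, 1.95e-05 and 0.000586). The main probe of BCL2L1 fell in SK-BR-3 (-0.43), though not without miR-644 replicate 1 (adjusted p = 0.0549), and another did not pass (-0.03, adjusted p = 0.926). The E-cadherin gene CDH1, expressed on the arrays labelled MCF-7 at 7279 to 8793, did not pass there (0.25, adjusted p = 0.0638) but did with dim genes left out (0.0341). CDH1 in the other lines and ZEB1 in every line lay near background, where no fall could be seen. CDH1 in MDA-MB-231 passed as higher without miR-644 replicate 1 (0.31, adjusted p = 0.0415). The main probe of SNAI2 rose in MDA-MB-231 (0.38, adjusted p = 0.00305), and another did not pass (0.08, adjusted p = 0.710). VIM and CDH2 rose on the arrays labelled MCF-7, with F test adjusted p = 1.97e-09 and 0.000280, although VIM lay near the ceiling in MDA-MB-231, where no rise could be seen. CDH2 lay near background in SK-BR-3, where a rise could be hidden. ESR1 fell on the arrays labelled MCF-7 (-0.75 ± 0.09) and lay near background in the other lines, so that no fall could be seen in them. ERBB2 fell in MDA-MB-231 (-0.57 ± 0.09), where its level was lowest, while its log2 fold changes of -0.12 in SK-BR-3 and -0.07 on the arrays labelled MCF-7, near the ceiling of the arrays, did not pass. The main probe of ACTB, another common reference gene, had log2 fold changes of -0.08 in MDA-MB-231, 0.03 in SK-BR-3 and -0.30 on the arrays labelled MCF-7 (adjusted p = 0.0184 for the last). Leaving out any of the 4 arrays of that line ended this call, and the level of this probe lay near the array ceiling in every line. Another ACTB probe fell on the arrays labelled MCF-7 (-0.41, adjusted p = 0.00149) and in MDA-MB-231 (-0.48), while the remaining one did not pass (0.01 and 0.09).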

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

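The tests of the HER2 amplicon genes against the other lines and of the separate GAPDH probes were chosen after their results had been seen, as were CDKN2A and the glycolysis medians of each line, and the other tests were written before.

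The effect of miR-644 differed between lines by limma's F test (adjusted p under 0.05) in 57 of 75 named genes, and in 6 of them the lines had calls in opposite directions. The range is the largest minus the smallest log2 fold change of the 3 lines. These 6 were ID3 (range 2.53), DKK1 (2.46), PLAU (2.46), GPER1 (2.24), PTGES (2.06) and S100A3 (2.05). PTGES rose in MDA-MB-231 and SK-BR-3 and fell on the arrays labelled MCF-7, while S100A3 fell in MDA-MB-231 and rose in SK-BR-3. The effect was lowest in MDA-MB-231 for ADAM19 (2.11), FLRT2 (1.77), BCKDK (1.75), PLOD1 (1.69), CCDC92 (1.69), TM9SF4 (1.40), JMJD8 (1.36), TRIOBP (1.27), GAPDH (1.21), RRP36 (1.12), COLGALT1 (1.08), CTBP1 (0.865), RPS28 (0.856), CTDSPL (0.653), SSR1 (0.515) and ERBB2 (0.501). It was highest in MDA-MB-231 for IFIH1 (1.64), DAAM1 (1.62), PLAC8 (1.53), SCOC (1.51), PGM2 (1.47), NDUFB5 (1.2), ENC1 (1.14), UGCG (1.12), TUFT1 (1.12), UHMK1 (0.823) and PDLIM7 (0.514).

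For other genes the highest or lowest effect was in another line, and the F test does not say which line differs. APRT, for example, fell on the arrays labelled MCF-7 (2214 and 2417 to 664 and 681) and in SK-BR-3 (1216 and 992 to 314 and 363). In MDA-MB-231 it read 1267 and 1406 on control and 1165 and 1339 on miR-644 arrays. FBXO32 likewise rose to a similar extent in SK-BR-3 and on the arrays labelled MCF-7. The effect was highest in SK-BR-3 for KRT15 (1.69), MT1G (1.63), CCL2 (1.43), NTN4 (1.36), ALDH1A3 (1.22), SPATS2L (0.998) and DHRS3 (0.897), and lowest there for PCP4 (2.13), TGFB3 (1.98) and BCL2L1 (0.510). On the arrays labelled MCF-7 it was highest for TWIST1 (1.81), HERC5 (1.72), VIM (1.57), FOS (1.52), SRPK2 (1.17), CITED4 (1.09), FBXO32 (0.862), CDH2 (0.715) and CDKN1A (0.610). It was lowest there for APRT (1.69), CEACAM6 (1.68), CRAT (1.37), SRARP (1.34) and ESR1 (0.798). Some of these ranges compare a fall with a line where no array reached the median level of all genes (136), so that no fall could be seen there. This holds for ESR1 and FLRT2 in the lines where they did not fall, for SRARP, CEACAM6 and PCP4 in MDA-MB-231, and for ADAM19, PLAU and S100A3 on the arrays labelled MCF-7. For ESR1, FLRT2, PCP4 and SRARP the difference between lines therefore says little about miR-644, while the others also differed between lines above that level. TGFB3 in MDA-MB-231 and CCDC92 in SK-BR-3 lay little above it, so that their ranges are limited too. Some rises were also set against lines where no array reached that level, and where background could hide a rise. This holds for TWIST1 in MDA-MB-231 and SK-BR-3, and for HERC5 and CDH2 in SK-BR-3. It also holds for PLAC8 in SK-BR-3, CCL2 in MDA-MB-231, and PLAC8, CCL2, MT1G and NTN4 on the arrays labelled MCF-7. ERBB2 in SK-BR-3 and on the arrays labelled MCF-7, and VIM in MDA-MB-231, lay near the array ceiling, where little change could be seen, so that their ranges are limited in the same way.

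By camera on the difference of the effects, 27 of 96 pairs of a list and 2 lines passed. With an estimated correlation 12 of these kept their call, and 15 lost it, with adjusted p from 0.0878 to 0.280. Kept were histone, interferon, unfolded protein response, cholesterol, early response and basal B genes for SK-BR-3 minus MDA-MB-231, S phase, interferon, unfolded protein response and cholesterol genes for the arrays labelled MCF-7 minus MDA-MB-231, and S phase and histone genes for those arrays minus SK-BR-3. The mean differences of log2 fold change, SK-BR-3 minus MDA-MB-231, were -0.414 for G2 and M phase, 0.139 for S phase, -0.343 for histone, -0.225 for interferon, 0.398 for unfolded protein response, -0.439 for cholesterol, 0.233 for glycolysis, 0.275 for TGF-beta, 0.398 for early response and 0.475 for basal B genes. For the arrays labelled MCF-7 minus MDA-MB-231 they were -0.477 for G2 and M phase, -0.499 for S phase, -0.348 for interferon, 0.287 for mesenchymal, 0.424 for unfolded protein response, -0.373 for cholesterol, 0.267 for glycolysis, -0.163 for oxidative phosphorylation, -0.199 for ribosome biogenesis, 0.342 for TGF-beta, 0.242 for Wnt, 0.346 for early response and 0.332 for basal B genes. For the arrays labelled MCF-7 minus SK-BR-3 they were -0.638 for S phase, 0.522 for histone, -0.169 for inflammatory and -0.228 for antigen presentation genes.

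More genes changed in MDA-MB-231 (5021) than in SK-BR-3 (2825) or on the arrays labelled MCF-7 (3231). The SD of replicate differences in the other lines was 1.001 times that of MDA-MB-231. The main fit uses the same spread estimate of a gene for every line, so a larger spread in the other lines could not explain its counts. Fits on the 4 arrays of a line estimate the spread within that line. In them 5139 genes changed in MDA-MB-231, 2572 in SK-BR-3 and 2907 on the arrays labelled MCF-7. For these fits the near equal SDs argue against a larger spread in the other lines as the cause. A common response of a different size in each line, such as from unequal uptake of the mimic, was tested by division by 1 slope per line (0.526 and 0.512). The number of differing genes was then 3494, or 85.03% of the number before. It includes genes near background or the ceiling in some lines, which can differ after any division. The same genes were not traced, so this number alone cannot measure the departure from a common response. Calls in opposite directions in 469 genes argue against a common response as the whole cause. A difference in size may still be part of the pattern. By the F test, effects differed between lines for 4109 genes. Whether responses specific to the lines, which the design names, account for the larger number in MDA-MB-231 was not tested. The chip position of the treatments cannot be told apart from the treatment.

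The arrays labelled MCF-7 had HER2 amplicon genes at a level not known of MCF-7, with 9 of 10 over 1 log2 above MDA-MB-231. The test written before the result used MTAP, which is deleted in MCF-7 and in MDA-MB-231. MTAP lay 0.9793 log2 above MDA-MB-231 (adjusted p = 1.16e-09), so the bound of more than 1, written as against MCF-7 RNA, was not met. The value was also above the 0.5 written as compatible with MCF-7 RNA, so MTAP by itself did not decide. In MDA-MB-231 MTAP is near background, which compresses the difference. CDKN2A, deleted with MTAP, was also higher though dim (0.50 log2, adjusted p = 0.000394). The rule that lets the amplicon genes decide between these bounds was set after the value was seen. By that rule the amplicon genes argue against MCF-7 RNA alone. SK-BR-3 RNA mixed in is argued against by genes abundant in SK-BR-3, whose 10th percentile was 0.2961% of the SK-BR-3 intensity. GRB7, under the ceiling, was higher than in SK-BR-3 (5731 against 3720). RNA of another HER2-amplified line with oestrogen receptor may explain these arrays, as a hypothesis found and tested on the same data.

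GAPDH, used in many laboratories as a reference gene, fell in every line. Scaling between arrays is argued against as the cause, since over 4 scalings and 3 lines the change closest to 0 was -1.074 log2. A fault of 1 probe is argued against because all 3 GAPDH probes fell past the threshold in all lines. A general fall of glycolytic transcripts by as much as GAPDH is argued against by the other 26 glycolysis and hypoxia genes, whose median average change was 0.0294 log2 (95% bootstrap interval -0.138 to 0.0693), and was -0.07 in MDA-MB-231 (-0.33 to 0.03), 0.03 in SK-BR-3 and 0.01 on the arrays labelled MCF-7, although SLC2A1 fell by 1.01 in the average and by 1.11 in SK-BR-3, where the GAPDH probes fell by 1.10, near the ceiling, to 1.88, and the list was called lower in MDA-MB-231 (mean -0.30, camera adjusted p = 0.00583, adjusted p = 0.160 with an estimated correlation). A direct effect of miR-644 on GAPDH may be one explanation, and neither it nor an effect through other genes was tested.

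For the average of the lines, a chance assignment of these arrays to the groups can be excluded as the source of the number of changed genes, but chance differences between cultures cannot, since the replicates may be technical (1 of 100 splits gave as many genes, the real one). The real split gave 5602 genes, and the highest of the other splits among 100 of the 108 possible gave 3713, in a split that turned the groups of whole lines around, whereas the highest of the others was 2597.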

How the results depend on the processing

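Fits without the arrays labelled MCF-7, on log2 values without quantile normalization, with a normexp background or with zeros as missing were chosen after seeing the data. CTBP1 fell past the threshold in each line and in the average under all alternatives run with its main probe. With another, dim probe it was -0.28 in the line labelled MCF-7 (adjusted p = 0.0678). Background may compress that value, and the cause was not tested. With a minimum of 1.5-fold, a stricter rule by construction, 1766, 607 and 753 genes changed in the lines, 559 in the average and 166 in all 3 lines. Without the arrays labelled MCF-7, 1526 genes changed the same way in 2 lines and 2675 differed, with fewer lines by construction. The averages of DKK1 (-0.033), ESR1 (0.035), ID3 (-0.130) and the S phase list (0.056) then had the other sign but did not pass. Their adjusted p were 0.813, 0.773 and 0.268 by limma and 0.295 by camera. Calls in the average were also lost for VIM (0.010), TWIST1 (0.040), CDH2 (0.050), CDKN1A (0.181) and the HER2 amplicon list (-0.172). Numbers of lists past the test were 3, 0, 1 and 0 (MDA-MB-231, SK-BR-3, labelled MCF-7, average) with an estimated correlation. With fry, which asks another question, they were 23, 25, 23 and 30 in the same order. With dim genes left out they were 6, 13, 4 and 9, where the cause was not tested. Calls lost with an estimated correlation cannot all be put down to correlated members. The basal B list in SK-BR-3 had an estimated correlation of -0.031, below the preset 0.01. Its camera p still rose from 6.82e-05 to 0.00525 before adjustment, and its call was lost. The HER2 amplicon difference between control arrays labelled MCF-7 and MDA-MB-231 was 3.01 and became 3.20 with a normexp background, which takes off background by construction. Leaving out 1 array at a time, where the lone array is assumed to vary like the other groups, gave 3943 to 5072, 1842 to 2871 and 2202 to 3285 genes in the lines, 5084 to 5400 in the average, 638 to 783 shared, 3203 to 3926 differing, and 8 to 9, 11 to 18, 8 to 10 and 11 to 13 lists. Of the single genes and lists, 8 lost their call with a normexp background, 17 lost and 6 gained it with dim genes left out, 4 and 2 with equal medians, 1 and 3 with an intensity trend, and 23 and 6 in at least 1 of the fits without 1 array. The lowest count in SK-BR-3 came without miR-644 replicate 1. Planned quantile normalization was the setting in use, array weights came out equal within each pair, and the alternatives for seed sites were not run. Signal over background limits what dim genes can show, since the floor near 75 lies close to the array medians of 111 to 113.

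The labels number replicates but do not say that equal numbers belong together, and deviations of equal numbers correlated at 0.026, -0.023 and 0.116. With the replicate block (a paired fit) 5074, 2849 and 3301 genes changed in the lines, 5660 in the average, 859 were shared and 4153 differed. The autophagy list in SK-BR-3 lost its call (adjusted p = 0.0509), and CDH1 in the average (0.0485) and H4C14 in SK-BR-3 (0.0399) gained one, where the cause was not tested.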

Other observations

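RPS28 and RPL23A fell in every line, while ribosomal protein genes as a list did not move more than other genes (mean log2 fold change 0.02 in the average of the lines, camera adjusted p = 0.814). Against no change fry called the list higher in the average (adjusted p = 0.0423) and in MDA-MB-231 (adjusted p = 0.0226). Of 35 other ribosomal protein genes, RPS23 rose (0.63 log2) and RPL3 fell (-0.19) in the average, and 33 did not pass. Of 17 microRNA pathway genes 5 rose and 4 fell in the average. By main probes TNRC6A (0.42), a partner of Argonaute, and TARBP2 (0.36), a partner of Dicer, rose, while AGO1 (-0.28) and the deadenylase gene CNOT7 (-0.28) fell. In MDA-MB-231, probes of TARBP2 passed in opposite directions, and it is among 58 such genes there. Such genes numbered 16 in SK-BR-3, 16 on the arrays labelled MCF-7 and 75 in the average. Among pro-apoptotic genes BMF (0.79) and BNIP3L (0.63) rose in the average, and BID (-0.54) and APAF1 (-0.40) fell. In MDA-MB-231 the fibronectin receptor gene ITGA5 fell by 1.99 log2 and the matrix protease gene MMP14 by 0.90. These genes were picked after their values were seen.

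Among 17202 probes without a gene symbol, which the comparisons of genes did not use, 4.27% changed in MDA-MB-231, 1.88% in SK-BR-3, 2.28% on the arrays labelled MCF-7 and 4.98% in the average.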
